A study of Allium cepa with 18 samples.

How the data were processed

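Which groups to compare, how to scale and which alternatives to try were fixed before the data were examined. The alternatives added after seeing the data were spike-in scaling, array weights estimated gene by gene, the fits without 2 and without 3 arrays, and the whole comparison of stored with before-curing arrays.

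Spot signals were taken as intensity, background-subtracted and spatially detrended, per the file headers, and were not normalized between arrays. Per the file headers they were extracted with Agilent Feature Extraction 10.5.1.1, and the submitters' processing notes give 10.5.1. Mean spot signal and median local background were also intensity per the file headers and served the normexp alternative (offset 50). The flags for well above background, saturation and non-uniformity were of unit other, 0 or 1 per spot, per the file headers. The deposited series table was in log2, per the authors, and its columns had medians and upper quartiles that were equal to 2 decimals (median 2.95 log2), as quantile normalization between arrays leaves them. Its scale and centring are known from its values only, and its software is not given in the sources used here. It held 13368 entries, of which 13310 matched probes of the arrays, with a Spearman correlation with the scanner signal of at least 1.00 after rounding.

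The arrays carried 15200 non-control spots for 13310 probes, which were all retained, in 5 probe sets of 11507, 1655, 102, 26 and 20 probes. Spots marked non-uniform were left out in 121 cells, and no spot was saturated. Spots of a probe were averaged in log2. The spread between spots of a probe was 0.0962 log2 (median over 18 probes with 106 spots). Because pooled detection was 41.8%, under 50%, the 75th percentile was taken over the 647 probes well above background on all 18 arrays, and that percentile ran from 61.1 to 23681. Tested were the 8277 probes well above background on at least 3 arrays; 5033 were not tested, and 1205 of these were seen on no array.

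Groups were fitted together in limma 3.58.1 under R 4.3.3, and single contrasts were called at adjusted p under 0.05 by limma's moderated test with Benjamini-Hochberg adjustment. SDs in the text are between the 3 arrays of a group. A change relative to the median is the log2 change less the median change of all tested probes. Factor tests of each gas averaged over the other gas, and joint tests used the moderated F statistic.

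At most 2 probes higher and 2 lower were named per comparison, those with the smallest p, and the same rule was used where none passed. This gave 48 named results. Where the dim arrays of a contrast of groups or of a gas were all not well above background, a lower bound of the fold change is given, from the bright arrays that measured the probe. Such a bound holds for the main processing only.

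Alternatives were normexp background correction, quantile normalization, median scaling, the 75th percentile over all probes, the authors' table, 3 other detection filters, slide as fixed or random block, scan day and replicate as blocks, eBayes with trend and robust, array weights, only the arrays compared, a stricter p, an added 2-fold limit, leaving out each array, leaving out the 2 arrays of slide 5, and those added later. The 18 arrays lay on 5 slides scanned on 4 days, and slides 1, 2, 4 and 5 held arrays of more than 1 group. Correlation within slides was 0.224 over all arrays and 0.00823 before curing.

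A self-test with simulated changes was run on the spread of these arrays, with 200 of 8209 probes changed in each of 20 runs. Of 4-fold changes 3.97% were recovered in the storage contrast and 2.79% in the ethylene contrast before curing, of 16-fold changes 37.7 and 37.6%, and of 64-fold changes 72.4 and 72.1%. False calls averaged 3.95 and 3.20 per run. The self-test gave each probe the same spread in every group and noise that was independent between probes. The measured median SD between replicates was 2.18 log2 in stored air and 0.41 in stored ethylene. These rates are therefore not those of the real contrasts.

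No gene set was tested. The 30 gene lists and the camera and fry tests were not run, because all descriptions of probes in the files read unknown and no annotation was used here.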

Results

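Bulbs of the onion cultivar Sherpa (*Allium cepa*) were profiled on 18 single-colour Agilent arrays, with 3 replicates, stated as biological in the series design, in each of 6 groups. Bulbs of 4 groups were sampled before curing, after 24 h at 20 °C in air (control), in ethylene at 10 µL per L, in 1-MCP (1-methylcyclopropene, a gas that blocks ethylene receptors) at 1 µL per L, or in both gases. Bulbs of the other 2 groups were cured for 6 weeks at 28 °C and then kept for 29 weeks at 1 °C, in air or in continuous ethylene at 10 µL per L. The aim of the series was to follow transcripts while sprout growth was held back by these gases. The 13310 probes of 60 nt are given by their IDs, because the files do not pair them with gene names.

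Detection differed widely between arrays. Well above background were 9.11% of the probes on air replicate 1 after storage, 85.7% on ethylene replicate 1 before curing and 25 to 68.7% on the other arrays. The mean log2 signal of 5 spike-in probes was 5.86 on air replicate 1 and 11.05 to 13.39 elsewhere, and over 647 probes seen on every array that array correlated with the others at 0.202 to 0.460, against 0.741 to 0.983 among the remaining 17. Air replicate 1 was kept, and counts without it are given beside each result; leaving it out also changed the scaling, since 2612 probes were then common to all arrays. Levels are log2 signal relative to the 75th percentile of the same 647 probes, and 8277 probes were tested. With 3 arrays per group the 95% interval of a typical comparison reached 2.41 log2 (5.30-fold) to either side, so that only large changes could be found. Air replicate 1 entered the spread shared by all groups. The median SD between stored air arrays was 2.18 with it and 0.53 without it.

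**Figure D1:**
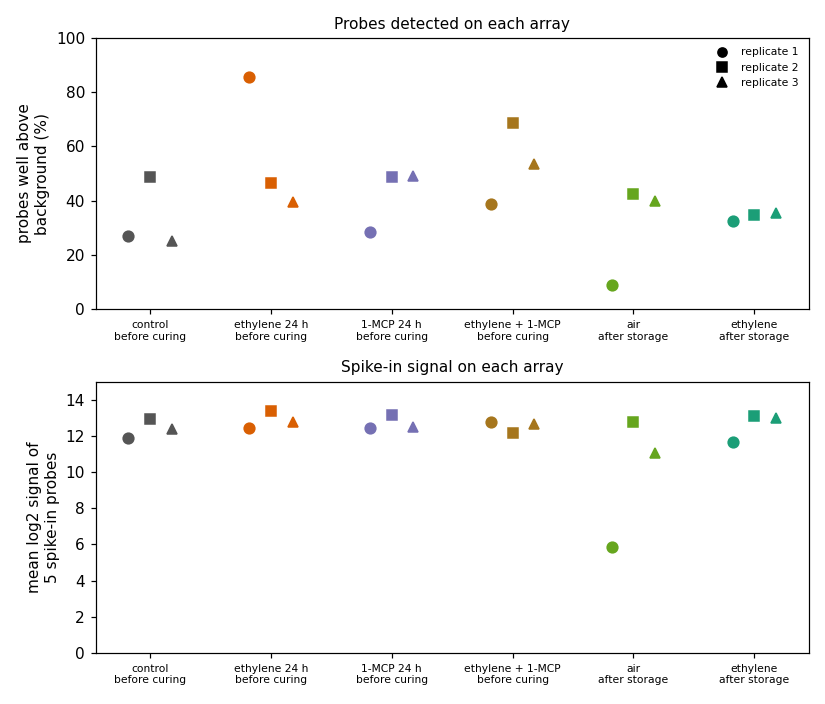
Percentage of probes well above background (upper panel) and mean log2 signal of 5 spike-in probes (lower panel) on each array, by group, with a marker for each replicate. Air replicate 1 after storage lies far below all other arrays in both panels.

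The first comparison asked which transcripts responded to 24 h of ethylene before curing. No single probe was resolved. The strongest candidate, CUST_1806_PI403527117, stood at -3.53 ± 0.40 (n = 3) in ethylene and -7.08 ± 1.09 (n = 3) in control, a difference of 3.54 log2. The median of all probes lay 0.88 above control, and relative to it this difference was 2.66. By limma's moderated test with Benjamini-Hochberg adjustment 0 probes passed (smallest adjusted p 0.812), with 275 at unadjusted p under 0.05 (268 higher) where chance would give 414. For CUST_1806_PI403527117 a fixed slide block gave 3.26, and within slide 1, where 3 ethylene arrays and 1 control array lay, the difference was 3.29. Without air replicate 1, 860 probes had unadjusted p under 0.05 (825 higher) and 0 passed; array weights let 0 pass as planned and 1366 when estimated gene by gene.

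The same question was asked of 1-MCP alone. CUST_1806_PI403527117 again stood above control, at -4.24 ± 0.76 (n = 3), a difference of 2.83 log2, or 2.63 relative to a median of 0.21. The test by limma with Benjamini-Hochberg adjustment passed 0 probes (smallest adjusted p 1.00), and 66 had unadjusted p under 0.05 (61 higher) where chance would give 414. For this probe the slide block gave 2.81, and within slide 2, with 2 arrays of each group, the difference was 2.74. Leaving out air replicate 1 gave 226 probes at unadjusted p under 0.05 (178 higher), with 0 passing. Replicate 3 of 1-MCP, also on slide 2, resembled the stored arrays on probes chosen for storage, as described below. It was kept here and in the other comparisons that use 1-MCP arrays. In this comparison 0 probes passed whichever single array was left out.

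Bulbs given ethylene and 1-MCP together were compared with control to ask whether the blocker removed the response. CUST_1806_PI403527117 stood at -3.35 ± 0.39 (n = 3), a difference of 3.73 log2, or 2.73 relative to a median of 1.00. The probe was thus the strongest candidate above control in each of the 3 treatments, and the interaction, the departure from additive effects, was -2.65 (adjusted p 1.00 by limma). By limma with Benjamini-Hochberg adjustment 0 probes passed (smallest adjusted p 0.631), and 568 had unadjusted p under 0.05 (560 higher) where chance would give 414. For CUST_1806_PI403527117 the slide block gave 4.17 and the difference within slide 2 was 4.16. Without air replicate 1, 966 probes had unadjusted p under 0.05 (875 higher) and 0 passed, while array weights let 3897 pass, or 2951 when estimated gene by gene.

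The 3 treatments shared the same control arrays, which alone makes their changes correlate. The changes in ethylene and in 1-MCP correlated at 0.531, those in ethylene and in the combination at 0.763, and those in 1-MCP and in the combination at 0.605, where groups simulated without any effect gave 0.500. The covariances were 0.370, 0.653 and 0.464, against 0.556 simulated. The simulated covariance exceeded 2 of the 3 measured ones, so these values do not settle whether the treatments shared a response beyond the control.

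Ethylene and 1-MCP were set against each other to ask where ethylene and the blocker of its receptors differ, at doses of 10 and 1 µL per L. The smallest p belonged to CUST_388_PI403527117, at -5.68 ± 0.63 (n = 3) in ethylene and -8.87 ± 0.94 (n = 3, seen on 2) in 1-MCP, a difference of 3.18 log2 (95% interval 1.18 to 5.19), but 0.05 after normexp background correction. In the other direction it belonged to CUST_69_PI404013531, at -11.00 ± 0.60 (n = 3) in ethylene and -7.50 ± 0.90 (n = 3) in 1-MCP, a difference of -3.50 log2 (95% interval -5.87 to -1.14), at least 3.68-fold. Passing limma's test with Benjamini-Hochberg adjustment were 0 probes (smallest adjusted p 1.00), and 69 had unadjusted p under 0.05 (61 higher, median shift 0.58) where chance would give 414. The slide block gave 1.63 for CUST_388_PI403527117 and -5.74 for CUST_69_PI404013531. No slide held arrays of both groups, so these values came only through other groups. With air replicate 1 left out 544 had unadjusted p under 0.05 (516 higher) and 0 passed; array weights let 0 pass, or 18 when estimated gene by gene. At this precision the test does not show that the gases act alike.

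What 1-MCP did to the ethylene response was asked with the combination against ethylene alone, and what ethylene did past the blocker with the combination against 1-MCP alone. Against ethylene alone CUST_2216_PI403527117 was higher by 2.39 log2 and CUST_3096_PI403527117 by 3.06 log2. Lower were CUST_1110_PI403527117 by -2.82 log2, but 0.74 with the slide block, and CUST_10796_PI403527117 by -3.64 log2, at least 2.96-fold. No slide held arrays of both groups, so the slide block parted them only through other groups. By limma with Benjamini-Hochberg adjustment 0 probes passed (smallest adjusted p 1.00), with 27 at unadjusted p under 0.05 (15 higher, 12 lower) and a median of 0.14. Against 1-MCP alone CUST_2905_PI403527117 differed by 4.67 log2, at least 5.37-fold, but by -0.22 after normexp background correction. Here 0 probes passed by limma (smallest adjusted p 0.959), with 74 at unadjusted p under 0.05 (70 higher) and a median of 0.70. The interaction had 0 past limma's test and 13 at unadjusted p under 0.05, where chance would give 414 in each case. Without air replicate 1 the numbers at unadjusted p under 0.05 were 129, 407 and 76 in the same order, with 0 passing in each, and array weights let 1556 probes pass in the combination against 1-MCP alone, or 525 gene by gene.

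Each gas was then tested over all 12 arrays before curing, which narrowed the typical 95% interval to 1.45 log2 (2.73-fold) to either side. For ethylene the clearest candidate was CUST_6980_PI403527117, well above background on 6 of 6 arrays with ethylene and 1 of 6 without, at -7.01 ± 1.55 in ethylene and -7.16 ± 1.09 in the combination against -10.17 ± 0.53 in control and -10.29 ± 1.07 in 1-MCP (n = 3 each). Its difference was 3.15 log2, or 2.35 relative to the median of 0.80, with the slide block 2.78, but -0.10 after normexp background correction. These sizes are not exact, because most arrays without ethylene did not measure the probe. By limma with Benjamini-Hochberg adjustment 0 probes passed (smallest adjusted p 0.309). At unadjusted p under 0.05 stood 1295 probes, 1286 of them higher, against 414 by chance. Mean detection was higher with the gas as well, at 57.3 ± 24.8% of probes in ethylene and 53.6 ± 14.9% in the combination. It was 33.5 ± 13.1% in control and 41.9 ± 11.8% in 1-MCP (n = 3 each). Ethylene replicate 1 had 85.7%, but replicates 2 and 3 had 46.7 and 39.7%, and 1-MCP replicate 3 had 49.0%. Array quality was thus not told apart from ethylene in the surplus of higher probes. After quantile normalization, which removes a common shift, 693 probes were at unadjusted p under 0.05 (489 higher, median 0.06), so the one-sidedness was partly lost. There were 986 (953 higher) without air replicate 1, and 0 passed. Without combination replicate 1 the number passing was 841, all higher, with CUST_6980_PI403527117 at adjusted p 0.0303 by limma, and array weights let 1611 pass, or 2430 gene by gene.

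For 1-MCP over the same 12 arrays the clearest candidate was CUST_69_PI404013531, well above background on 6 of 6 arrays with 1-MCP and 0 of 6 without. It stood at -7.50 ± 0.90 in 1-MCP and -8.99 ± 0.43 in the combination, against -10.36 ± 0.27 in control and -11.00 ± 0.60 in ethylene (n = 3 each). The measured difference was 2.43 log2, at least 1.90-fold, or 2.27 relative to the median of 0.16, with the slide block 2.40, and 1.10 after normexp background correction. For 1-MCP 0 probes passed by limma with Benjamini-Hochberg adjustment (smallest adjusted p 1.00), with 80 at unadjusted p under 0.05 (50 higher) where chance would give 414. There were 110 (53 higher) without air replicate 1, and 0 passed. Across the 4 groups before curing limma's joint test passed 0 probes, with 257 at unadjusted p under 0.05; without air replicate 1 it passed 0, and array weights let 2141 pass, or 1856 gene by gene.

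**Figure D2:**
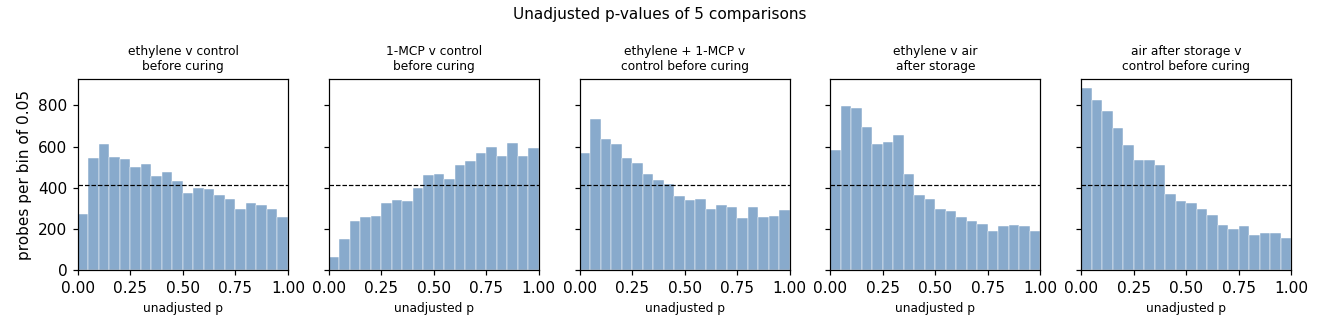
Number of probes by unadjusted p in bins of 0.05 for 5 comparisons, with the dashed line at the number expected if no probe changed. In 1-MCP against control few probes have low p, and in the last 3 panels the first bin lies above the line.

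The main question for storage was what continuous ethylene did to bulbs kept for 35 weeks including curing. Transcripts of 2 probes were lower in ethylene than in air in the main fit. Stored ethylene arrays lay on slides 1, 1 and 4 and stored air arrays on slides 4, 5 and 2. Only slide 4 held both, so gas and slide were otherwise parted only through other groups. CUST_10358_PI403527117 (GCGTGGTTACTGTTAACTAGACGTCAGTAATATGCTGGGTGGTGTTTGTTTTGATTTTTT) stood at -11.05 ± 0.07 (n = 3) in ethylene and -3.99 ± 1.66 (n = 3) in air, a change of -7.06 log2. It was well above background on all 12 arrays before curing, on 2 of 3 in stored air (mean -3.38, at least 47.5-fold over stored ethylene) and on 0 of 3 in stored ethylene. CUST_361_PI403527117 (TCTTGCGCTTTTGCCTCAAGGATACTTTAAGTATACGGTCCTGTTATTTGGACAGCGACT) stood at -10.76 ± 0.96 (n = 3) in ethylene and -5.32 ± 0.94 (n = 3) in air, a change of -5.44 log2, and was seen on 2 of 3 air arrays (mean -5.22, at least 13.2-fold over stored ethylene), 0 of 3 ethylene arrays and 3 of 12 before curing. Its group means before curing lay between -11.05 and -9.56, near that in stored ethylene, so that it was high in stored air only, whereas CUST_10358_PI403527117 was low in stored ethylene only. Air replicate 1 measured neither probe and entered the means of 3 arrays at its scaled floor, so the bounds hold for the other 2 air arrays only. They set the mean of the arrays that measured a probe against the higher of its own signal and the lowest signal among probes well above background on each ethylene array. The bounds apply to the main processing only. Over all settings the change ran from -7.89 to -4.15 log2 for CUST_10358_PI403527117 and from -6.26 to -3.20 log2 for CUST_361_PI403527117. By limma with Benjamini-Hochberg adjustment both had adjusted p 0.00969, and 0 probes were higher; 583 had unadjusted p under 0.05 (565 lower) where chance would give 414.

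The median of all probes lay at -1.21 in stored ethylene against air, and relative to it the changes of CUST_10358_PI403527117 and CUST_361_PI403527117 were -5.86 and -4.23. That shift came from air replicate 1: without it the median was 0.04, 309 probes had unadjusted p under 0.05 (190 higher), and the same 2 probes passed with -7.59 (adjusted p 0.0141 by limma) and -5.45 (adjusted p 0.0138). Neither passed with a fixed slide block (-7.36 and -5.11, adjusted p 0.0764 and 0.107 by limma), and within slide 4, which paired air replicate 1 with ethylene replicate 1, neither probe was above background on either array, so that the difference of -5.82 for each was only the gap between the scaled floors of the arrays (75th percentile 61.1 and 5074) and measured neither probe. The count fell to 0 with normexp background correction, quantile normalization, the 75th percentile over all probes, the authors' table, both stricter detection filters, a scan day block, the 6 arrays alone, the 2 arrays of slide 5 left out, or without air replicate 2, ethylene replicate 1 or ethylene replicate 3, and was 1 without ethylene replicate 2, 5 without air replicate 3, 4 without 1-MCP replicate 3, 1748 with array weights and 43 with weights gene by gene.

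**Figure D3:**
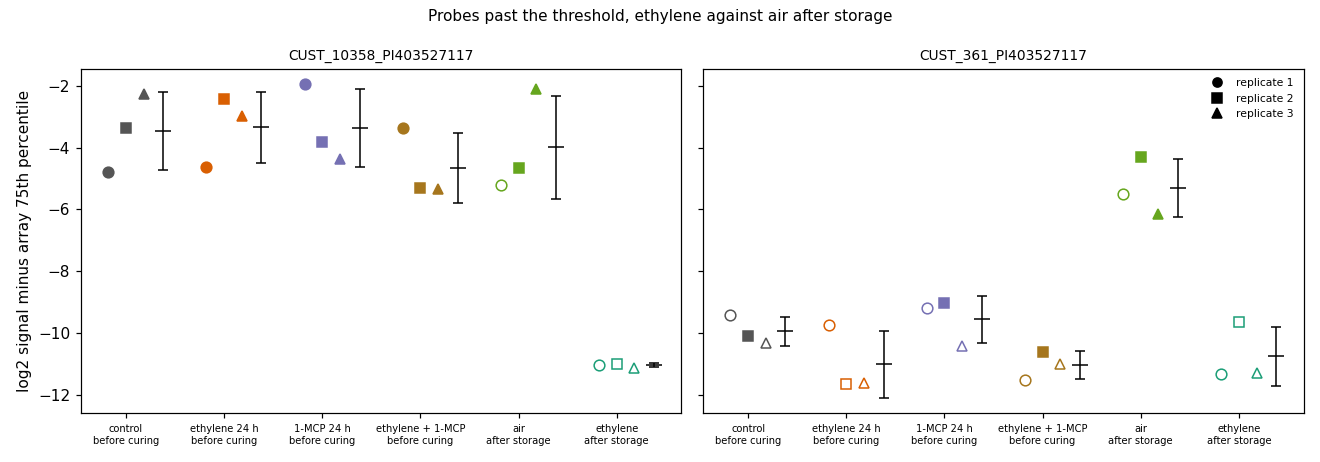
Log2 level relative to the 75th percentile of the common probes on each array for CUST_10358_PI403527117 and CUST_361_PI403527117, filled where well above background and open where not, with group mean ± SD as black bars. Both probes are at the floor on all 3 arrays stored in ethylene.

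Air storage was set against control before curing to ask what curing and cold storage did without ethylene. The lowest p belonged to CUST_361_PI403527117, higher by 4.64 log2 and well above background on 2 of 3 air and 1 of 3 control arrays, and CUST_11333_PI403527117, lower by -5.69 log2 (-5.44 ± 0.24 against 0.25 ± 0.65, n = 3 each), both with adjusted p 0.115 by limma. CUST_11333_PI403527117 was well above background on 2 of 3 air arrays, so its air mean and SD include an array that did not measure it. CUST_11372_PI403527117 stood 5.88 log2 higher (-4.97 ± 0.19 against -10.85 ± 1.23, n = 3 each), with air replicate 1 again at its scaled floor and the 2 air arrays that measured it (mean -4.89) at least 17-fold over control, and CUST_42_PI404013531 5.15 log2 lower (-2.14 ± 0.68 against 3.01 ± 0.70, n = 3 each), with adjusted p 0.196 by limma. Relative to the median of 1.20, again set by air replicate 1 (-0.07 without it), these were 3.44, -6.89, 4.68 and -6.35 in the order given. In all, 0 probes passed by limma with Benjamini-Hochberg adjustment, with 883 at unadjusted p under 0.05 (778 higher) where chance would give 414. The slide block gave 4.43, -5.46, 6.95 and -5.51, and within slide 2, with 1 air and 2 control arrays, the differences were 3.62, -5.26, 6.23 and -5.0.

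For the same contrast of air storage with control, all 4 probes passed when 1-MCP replicate 3, which belongs to neither group, was left out (CUST_361_PI403527117, CUST_11372_PI403527117 and CUST_42_PI404013531 at adjusted p 0.0301 and CUST_11333_PI403527117 at 0.00536 by limma), and the count was 9. It was 2 without air replicate 1, 1 without stored ethylene replicate 3, 2 without the arrays apart in spike-in signal, 26 without those and 1-MCP replicate 3, 1 with the percentile over all probes, 2 and 1 with the stricter filters, 1 with a scan day block, 7 with eBayes trend and robust, 1902 with array weights and 19 gene by gene.

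Whether long ethylene differed from short ethylene was asked by subtracting the 24 h effect from the storage effect. CUST_10358_PI403527117 gave -7.20 log2, or -5.06 relative to the median of -2.13, having stood at -3.34 in ethylene and -3.47 in control before curing, and the slide block gave -7.04 (adjusted p 0.173 by limma). These sizes are not exact, because the probe was at the floor on all 3 stored ethylene arrays and on air replicate 1. By limma with Benjamini-Hochberg adjustment 0 probes passed (smallest adjusted p 0.336), and 1211 had unadjusted p under 0.05 (1199 lower) where chance would give 414, or 675 after quantile normalization (median 0.13). Without air replicate 1, to which this contrast owes much of its shift, the median was -0.53, 556 had unadjusted p under 0.05 (93 higher), and 0 passed. The typical 95% interval of this double difference reached 3.40 log2 (10.6-fold) to either side. With eBayes trend and robust 3 probes passed, with array weights 1 and gene by gene 1177.

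A joint test asked which transcripts differed anywhere among the 6 groups. Past limma's moderated F test with Benjamini-Hochberg adjustment were 7 probes (adjusted p 0.0199 to 0.0429; 442 at unadjusted p under 0.05), and 5 of them had their lowest mean in stored ethylene. Among the 5, CUST_42_PI404013531 was low in both stored groups, at -2.43 in ethylene and -2.14 in air against 1.85 to 3.01 before curing. CUST_2252_PI403527117 stood at 1.00 in control, -2.88 in stored air and -9.96 in stored ethylene, and CUST_97_PI404013531 at -2.37 in stored air and -9.97 in stored ethylene. Each of the latter 2 was well above background on 1 of 3 stored ethylene arrays, so those levels are not exact. Their means lay close in every group, and whether they measure the same transcript was not tested. CUST_361_PI403527117 was highest in stored air, and CUST_6756_PI403527117 was higher in both stored groups than before curing. Each of these 2 probes was well above background on 2 of 3 stored air arrays, so their stored air levels are not exact. The count was 0 with a slide block, with the percentile over all probes and at adjusted p 0.01, 1 with normexp, 2 without a detection filter, 4 with a replicate block, 28 with quantile normalization or the authors' table, 19 and 11 with stricter filters, 103 with eBayes trend and robust, 5312 with array weights, 4131 gene by gene, 19 without the 2 arrays apart in spike-in signal, and 163 without 1-MCP replicate 3 as well. It was 27 without air replicate 1, 40 without 1-MCP replicate 3, 0 without ethylene replicate 3 before curing or any of stored ethylene replicates 1, 2 and 3, 1 without control replicate 1 or 3 or ethylene replicate 2, 2 without air replicate 2, 3 without control replicate 2, ethylene replicate 1, 1-MCP replicate 2 or combination replicate 1, and 4 without combination replicate 2 or 3.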

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

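All tests of explanations in this part were chosen only after the result was seen.

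Of 12 sets tested for an array apart from its group, with 6 arrays in each and a Dixon critical value of 0.625, 5 had such an array, where chance gives about 1 in 20 groups. For the lowest spike-in, ethylene replicate 1 before curing read 6.47 against 1.22 to 2.17 on the other arrays given ethylene, and for negative controls 70.1 against 42.0 to 52.3. Control replicate 3 before curing read 53.0 on negative controls against 40.9 to 43.2. Stored air replicate 1 had 9.11% of probes well above background against 32.6 to 42.4%, and spike-in signal of 5.86 against 11.05 to 13.1. Both negative-control readings fell on slide 1, where all arrays read 50.0 to 70.1 and no array of another slide read over 44.0.

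Stored air replicate 1 stood apart in spike-in signal, 5.19 log2 below the lowest other array. Since spike-ins are added in equal amount, labelling or hybridization of that array likely failed. A displaced spot grid was excluded, because the best displaced grid correlated with the other array of the slide at 0.0174 against 0.740 in place. A fault of the whole slide was excluded, because the other array on it had spike-in signal of 11.7. A poor RNA sample was not tested.

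Ethylene replicate 1 before curing had the most probes well above background. Its lowest spike-in lay 4.25 log2 above the highest other array, which points to raised unspecific signal on that array. Its upper spike-in signal of 12.4 lay within 11.05 to 13.39, the range without stored air replicate 1, so the bright spike-ins were not raised. Its 75th percentile over the common probes was the highest of all arrays (23681, next 17665). Stronger signal of the sample itself was therefore not excluded. A part of the surplus of probes with higher signal in ethylene may come from this array.

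1-MCP replicate 3 before curing resembled the stored arrays on probes chosen for storage, though over all 2612 probes its median correlation was 0.878 with 5 stored arrays and 0.856 with the other before-curing arrays, the highest being 0.956 with stored air replicate 2 and the next 0.898 with control replicate 2. A storage score over 200 of these probes, chosen without the scored array, 0 at the before-curing mean and 1 at the stored mean, was 0.754 for it, within 0.648 to 1.06 of the stored arrays other than air replicate 1. The 5 other arrays given 1-MCP scored at most 0.132, and the other before-curing arrays on the slide of 1-MCP replicate 3 at most 0.319. When the probes were chosen, the remaining arrays of these kinds counted as before curing, which favours low scores. An effect of 1-MCP or of the slide was therefore not seen in the other arrays, but was not excluded. A wrong label or stored tissue in the sample could explain the score. Variation from bulb to bulb was not tested.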

How the results depend on the processing

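The tests of pairing and of settings added later, which are spike-in scaling, weights gene by gene and the fits without 2 or 3 arrays, were chosen only after the result was seen.

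Of 1857 values for 48 named results 1764 kept their direction and their side of the adjusted p threshold in other settings, 25 no longer passed, 61 newly passed and 7 were reversed, and the cause was not tested. Only 2 of the 48 passed in the main fit. For the others, keeping their side meant not passing again, so the 1764 does not measure stability. The 25 that no longer passed all belonged to these 2, which passed in 26 and 25 of 38 settings. Sizes varied widely where direction was kept: CUST_388_PI403527117 in ethylene against 1-MCP ran from 0.05 to 3.81 log2 and CUST_6691_PI403527117 in ethylene against control from 0.25 to 3.81. After normexp CUST_5579_PI403527117 in 1-MCP against control turned to 0.10, CUST_2905_PI403527117 and CUST_10790_PI403527117 in the combination against 1-MCP to -0.22 and -0.38, CUST_6980_PI403527117 in ethylene present to -0.10, and CUST_10796_PI403527117 and CUST_9950_PI403527117 in 1-MCP present to 0.18 and 0.16. With a fixed slide block CUST_1110_PI403527117 in the combination against ethylene turned to 0.74.

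The 2 probes lower in stored ethylene than in stored air became 0 with normexp background correction, quantile normalization, the 75th percentile over all probes, the authors' series table values, probes detected on every array of a compared group, probes detected on all 18 arrays, slide as a fixed block, scan day as a fixed block, only the arrays compared, and without the 2 arrays of slide 5. Array weights gave 1748 (572 higher, 1176 lower) and weights gene by gene 43 (20 higher, 23 lower). Leaving out each array gave 0 to 5. In 26 of 38 settings CUST_10358_PI403527117 passed, with adjusted p from 2.55e-07 to 0.738 by limma, and CUST_361_PI403527117 in 25 of 38, from 3.44e-07 to 0.738.

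The 0 probes in stored air against control became 1 with the percentile over all probes, 2 with probes detected on every array of a compared group, 1 with probes detected on all 18 arrays, 1 with a scan day block, 7 with eBayes trend and robust, 1902 with array weights, 19 gene by gene, 2 without 2 arrays, 26 without 3 arrays, and 0 to 9 leaving out each array. In long against short ethylene the 0 became 3 with eBayes trend and robust, 1 with array weights and 1177 gene by gene.

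Before curing, array weights moved counts of 0 to 3897 for the combination against control, 1556 for the combination against 1-MCP, 1611 for ethylene present and 2141 for the 4 groups. Gene by gene they gave 1366 for ethylene against control, 2951, 525, 2430 and 1856 for those just listed, and 18 for ethylene against 1-MCP. The weights ran from 0.0322 to 7.55 and their estimation did not reach its tolerance. Leaving out each array gave 0 to 841 for ethylene present and 0 to 0 for the other contrasts before curing.

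The 7 probes over 6 groups became 1 with normexp, 28 with quantile normalization, 28 with the authors' table, 0 with the percentile over all probes, 2 with no filter, 19 and 11 with the group filter and the filter on all 18 arrays, 0 with slide as a fixed block, 4 with the replicate block, 103 with eBayes trend and robust, 5312 with array weights, 4131 gene by gene, 0 at adjusted p 0.01, 19 without 2 arrays, 163 without 3 arrays, and 0 to 40 leaving out each array.

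Replicate numbers were checked for pairing between groups. Over 45 pairs of the same number the median correlation was -0.0585, with 14 over 0.1, against 0.0139 for 90 pairs of other numbers, and 3 of 18 arrays were closest to their own number. These values gave no sign of pairing, so replicates were treated as unpaired, though a pairing was not excluded. The replicate block left 2 probes in stored ethylene against air and 4 over 6 groups.

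The 30 gene lists and the camera and fry tests were not run.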

Other observations

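All tests in this part, and the comparison of stored with before-curing arrays, were chosen only after the result was seen. The other comparisons whose counts are set against splits were planned.

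Stored bulbs differed from bulbs before curing in many transcripts. By limma's moderated test with Benjamini-Hochberg adjustment 151 probes passed, 67 higher (median 3.03 log2) and 84 lower (median -2.92 log2). CUST_2079_PI403527117 was 6.58 log2 higher in stored bulbs (1.27 against -5.31) and CUST_6756_PI403527117 3.19 higher (-4.70 against -7.89). CUST_42_PI404013531 was lower by -4.73 (-2.29 against 2.44) and CUST_11333_PI403527117 by -4.45 (-5.32 against -0.87), each of the 4 with adjusted p 0.00235 by limma. CUST_6756_PI403527117 and CUST_11333_PI403527117 were well above background on 5 of 6 stored arrays, so their stored means are not exact. With a fixed slide block 22 probes passed, 18 of them shared, among them CUST_2079_PI403527117 (7.0, adjusted p 0.0210 by limma), CUST_6756_PI403527117 (3.41, 0.0387), CUST_42_PI404013531 (-4.71, 0.0459) and CUST_11333_PI403527117 (-4.42, 0.0459). The contrast pools both storage gases and joins curing, cold and 35 weeks of time, which these groups cannot part.

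Only 2 of 100 splits of the 18 arrays, the real split counted, gave as many probes as stored against before curing. The splits moved arrays freely across slides, and the contrast was chosen after the data were seen. A share this low therefore does not exclude chance as the source of the 151. The highest other split gave 1692, which points to a structure of the samples other than storage. Its set of 6 held stored air replicate 1, ethylene replicate 1 and 1-MCP replicate 3, the arrays doubted elsewhere in this section, and array quality was not told apart from differences between bulbs there. Over 647 probes, arrays of the same kind correlated more than arrays of different kind in an exact permutation test over 18564 splits (p 0.000108, adjusted p 0.000323 by Benjamini-Hochberg over 3 tests). Within slides the p of this permutation test was 0.00556, the smallest that 180 arrangements allow (adjusted 0.0167). Slides alone therefore did not account for the difference in the profile of these 647 probes. For single probes slides were not excluded, since 22 passed with a fixed slide block, though all 151 kept their direction. The same exact permutation test over 924 splits gave p 0.411 for ethylene before curing and 0.593 for 1-MCP before curing, and could not tell whether either gas moved the whole profile.

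The count of 151 depended on settings and arrays. It was 5 with normexp, 37 with spike-in scaling, 418 with quantile normalization, 420 with the authors' table, 321 with the percentile over all probes, 74 without a filter, 241 and 64 with stricter filters, 287 with eBayes trend and robust, 2948 with array weights, 2634 gene by gene and 51 without the 2 arrays of slide 5. Leaving out single arrays gave 453 without stored air replicate 1, 42, 78 and 78 without stored ethylene replicates 2, 1 and 3, and 99, 100 and 229 without 1-MCP replicates 1, 2 and 3. Without the 2 arrays apart in spike-in signal it was 385, and without 1-MCP replicate 3 as well 731.

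A small set of probes dropped below detection after storage in ethylene. Over the 17 arrays without stored air replicate 1, 17 probes were well above background on the other 14 arrays and on none of the 3 stored ethylene arrays, and no group before curing had such a probe. Of all 680 sets of 3 arrays 4 had as many (exact permutation p 0.00588). The other 3 sets, with up to 184 probes, were drawn from the arrays with the fewest detected probes. The 17 probes lay -4.17 log2 (SD 1.64) below the other arrays at the median, against -2.30, -2.08 and -1.48 in the other 3 sets. These are differences to the scaled floor, which differs between arrays, so lower sensitivity of the 3 arrays was not excluded.

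For each pair of 3-array groups only 10 splits exist, the real split counted, too few for a share under 0.05. Stored ethylene against stored air had 2 probes, and 1 of 10 splits, the real split itself, had as many, the highest other having 0. The other contrasts of a pair of groups had 0, a count that all 10 of 10 splits must reach, so the splits decide nothing there; the highest other was 50 for 1-MCP against control and 0 for the rest.

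Where 100 splits were drawn and the real count was 0, all 100 reach it by construction, so these splits say nothing on chance. This holds for the interaction (highest other 0), the long against short ethylene effect (291), ethylene present (1825), 1-MCP present (2967) and the 4 groups before curing (2577). For the 6 groups 6 of 100 splits gave at least the real 7, so chance was not excluded, the highest other giving 3492. Splits with so many calls point to a structure of the samples, and array quality can be part of it: the largest ethylene split set arrays with 54.7% of probes detected on average against arrays with 38.5%. The real ethylene groups differed about as much, with 57.3 and 53.6% detected against 33.5 and 41.9%.

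Probes with the same sequence behaved alike. Over 45 such pairs the median difference in the log2 change between stored ethylene and stored air was 0.22, against 1.04 in random pairs. Spot noise in these pairs was thus small beside the differences between random pairs. Agreement of transcripts was not told apart from agreement at the floor.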
